A study of Mus musculus with 25 samples.

How the data were processed

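The deposited table held 30749 genes in 21 libraries, with columns for 21 of the 25 labelled samples; the 4 normal brain microglia samples, and the 5 comparisons planned against them, were not analysed here. From the values, the table is on a log2-like scale with a floor of 4.22 for a gene without reads, the form the authors' tool DESeq2 gives after a variance-stabilising transformation. The design had assumed normalised counts, so the test was chosen for log2 values. Per the submitters' processing notes, reads were aligned with STAR 2.7.8a to mm10 and the counts were handled with DESeq2, whose version was not given. Per the labels' protocols, total RNA was extracted with TRIzol and chloroform, cleaned with miRNeasy Micro kits on a QIAcube and amplified with SMART-Seq v4 Ultra Low Input. The labels name no mouse strain, no sort gate and no strand of the reads, so genes that overlap on opposite strands may share reads.

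The transformation was inverted in closed form. Every deposited value came back as a whole number of reads to within 1e-06 with 1 size factor per library, and these factors differed from median-of-ratios factors of the same 21 libraries by at most 3.1e-13%. In 21 simulated libraries of 20000 genes the inversion recovered 100% of reads. Recovered totals were 26530069 to 50365607 reads, size factors 0.62 to 1.55, and the 10 most abundant genes took 6.8% to 26.1% of reads. The first and second principal components carried 42.5% and 9.6% of the variance. Of the table's symbols 96.3% matched RefSeq GRCm38.p6, from which chromosome positions were taken.

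Normalised counts were taken as log2(count + 1), and genes with at least 10 in at least 3 libraries were kept, 17216 in all. limma-trend was fitted with 1 mean for each of the 8 groups of tumour type, model and cell type, and groups were weighted equally within a contrast, so a fitted fold is not the ratio of the pooled means. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 29 gene lists, fixed with the design, were tested with camera at an inter-gene correlation of 0.01, and again with the correlation estimated from the data. Members were also adjusted over their list alone. Genes named in the text are genes fixed in the design, the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 on the higher side, leaving out predicted and unnamed genes and receptor segments, and up to 4 members of each described list with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen. Where a group had no reads at all, a lower bound on the fold is given against 3 reads per library. Tools were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

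The method was tried on simulated libraries with 200 changed genes and the real group sizes. For MDM against microglia (16468 genes) it recovered 41.7%, 71.4% and 92.6% of genes changed 2-, 4- and 16-fold with the right sign, and 3 of 133 called genes had not been changed. For tumour type in microglia (16469 genes) the shares were 25.8%, 70.3% and 93.4% (6 of 125), and for model in microglia (16472 genes) 17.2%, 59.4% and 83.1% (9 of 112). In transplanted MDM by tumour type (16459 genes) they were 4.4%, 41.5% and 65% (4 of 73), and in type 1 MDM by model (16437 genes) 3.4%, 31.3% and 61.3% (7 of 68). The interactions recovered 1.3%, 28.6% and 59.6% (type by model in microglia, 16471 genes, 4 of 57), 0%, 30.3% and 55% (cell type by tumour type, 16465 genes, 2 of 55) and 3.5%, 21.4% and 63.5% (cell type by model, 16463 genes, 4 of 61). Without any changed gene, 3 genes were called in the tumour type comparison of microglia, 1 in the model comparison of type 1 MDM and 0 elsewhere, and 1 of 29 lists was called in the type by model interaction. Simulated genes were drawn independently of each other and without RNA of other cells, so these rates cannot stand for the real libraries. In the real data 15 of 115 list calls were the same with an estimated correlation.

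Alternatives tried were a pseudocount of 8, a filter at 50, no filter, quantile normalization, rescaling to the same total, array weights, fits with only the compared groups, sex as a covariate, a replicate block, an additive model, each library left out in turn, limma-trend on the deposited values and voom on the recovered reads. Libraries rich in transcripts of other cells were also left out together.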

Results

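RNA of sorted tumour-associated macrophages was measured in mouse models of glioblastoma, an aggressive brain tumour. Monocyte-derived macrophages (MDM, cells that enter the tumour from the blood) and microglia (the resident macrophages of the brain) were sorted from tumours labelled type 1 or type 2, which had arisen spontaneously or had been transplanted. The 21 libraries analysed were 3 microglia libraries from each of the 4 tumour classes, and 2, 4, 1 and 2 MDM libraries from type 1 spontaneous, type 1 transplanted, type 2 spontaneous and type 2 transplanted tumours. The 4 libraries of normal brain microglia were not analysed here. The series title names tumour progression and these macrophages as its subject. The design compares cell types, tumour types and models. Between 16297 and 21435 genes were detected per library. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Levels are normalised read counts, given as mean ± SD. Fold changes are on the log2(normalised count + 1) scale and are given with ± the standard error of the fit. Each adjusted p comes from limma-trend with Benjamini-Hochberg adjustment over 17216 genes.

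The MDM and microglia libraries differed in their lineage markers, in the direction of the sort. Tmem119, a surface protein of microglia encoded on chromosome 5 of GRCm38 (113793729 to 113800396 in RefSeq), was 19.8-fold lower in MDM, at 11010 ± 12080 normalised counts (n = 9) against 177700 ± 40030 in microglia (n = 12), with a log2 fold change of -4.31 ± 0.29, adjusted p = 7.5e-09. P2ry12, an ADP receptor of resting microglia, differed by -5.35 ± 0.52, adjusted p = 2.4e-07, and Sall1, a transcription factor of microglial identity, by -4.71 ± 0.46, adjusted p = 2.5e-07. In the other direction, Ccr2, the chemokine receptor of inflammatory monocytes, stood at 19230 ± 16170 in MDM and 557 ± 781 in microglia (5.85 ± 0.61, adjusted p = 5.1e-07). Itga4, the integrin subunit CD49d of cells recruited from the blood, was 48.6-fold higher in MDM (5.60 ± 0.40, adjusted p = 1.1e-08). Cx3cr1, the fractalkine receptor, was lower in MDM (-2.70 ± 0.20, adjusted p = 1.8e-08), as were Csf1r, the receptor for macrophage growth factor (-1.98 ± 0.27, adjusted p = 9.9e-06), and the integrin Itgam, which encodes CD11b (-1.44 ± 0.29, adjusted p = 0.00046). Ptprc, which encodes CD45, was higher in MDM (0.95 ± 0.17, adjusted p = 2e-04). The plot of marker genes by library shows these differences.

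**Figure D1:**
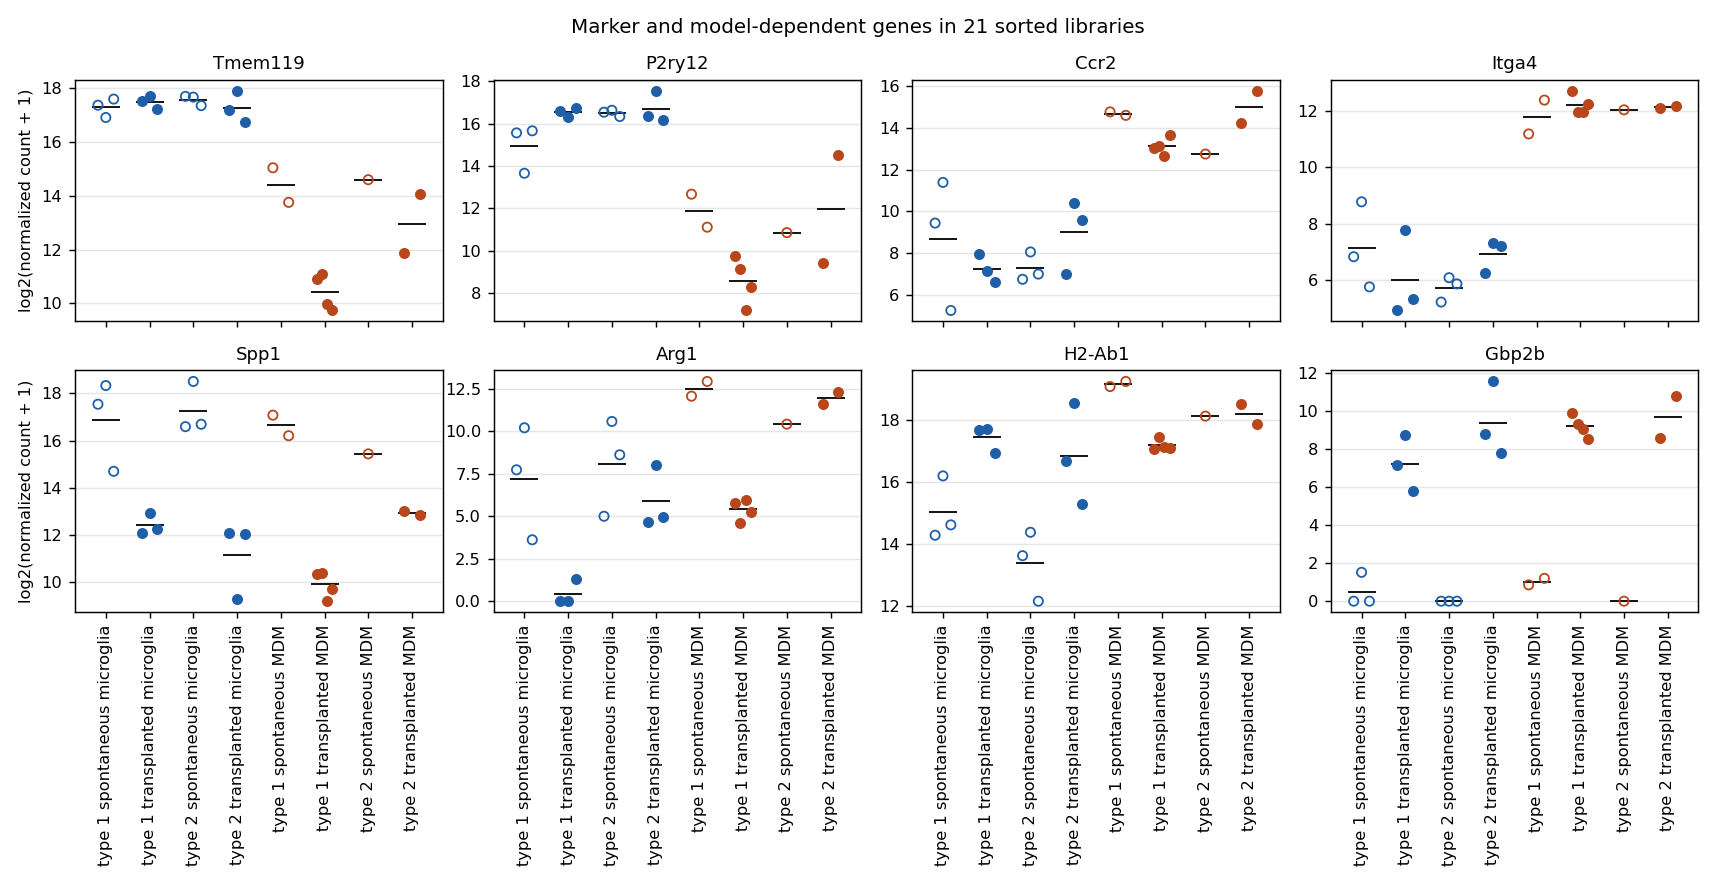
Normalised read counts of the 21 libraries on the log2(count + 1) axis for 8 genes, a point per library (blue microglia, orange MDM, open spontaneous, filled transplanted) with black bars for group means. Spp1 was at most 8350 normalised counts in the 12 transplanted libraries and at least 26600 in the 9 spontaneous ones, and Gbp2b was at most 1.87 in the spontaneous libraries and at least 55.2 in the transplanted ones.

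Of 27 tested genes of homeostatic microglia, 26 were lower in MDM and 1 was higher, the same counts as when adjusted over the list alone (median log2 fold change -4.03, camera adjusted p = 1.5e-19, and adjusted p = 0.12 with an estimated correlation). P2ry13, another ADP receptor, changed by -3.86 ± 0.31. The list of monocyte-derived macrophages had 31 of 32 members higher and 0 lower, 31 and 0 when adjusted over the list alone (camera adjusted p = 2e-18, and adjusted p = 0.12 with an estimated correlation). Its members included the calcium-binding S100a4 (6.54 ± 0.46), the LIM-domain gene Crip1 (4.89 ± 0.25) and the leukocyte actin-binding gene Lsp1 (4.03 ± 0.21). MHC class II genes, which present antigen to helper T cells, were higher in MDM for 8 of 11 members and lower for 0 (camera adjusted p = 0.00056, and adjusted p = 0.36 with an estimated correlation), with H2-Ab1 at 2.48 ± 0.39, adjusted p = 4e-05 and Ciita, the master activator of these genes, at 4.30 ± 0.41, adjusted p = 1.8e-07. Complement genes went the other way, 10 of 15 lower and 1 higher (camera adjusted p = 0.00032, and adjusted p = 0.13 with an estimated correlation). C1qa, part of the first component, changed by -3.40 ± 0.32 and C4b by -3.65 ± 0.33, while Cfp, which encodes properdin, was higher (5.32 ± 0.39).

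Lysosome and phagocytosis genes were lower in MDM for 22 of 27 members and higher for 0 (camera adjusted p = 6.1e-11, and adjusted p = 0.12 with an estimated correlation). Examples were the protease genes Ctsl (-3.35 ± 0.25) and Lgmn (-2.92 ± 0.28) and the phagocytic receptor gene Mertk (-3.20 ± 0.30). Of 27 genes of disease-associated microglia, 17 were lower and 2 higher (camera adjusted p = 2.1e-06, and adjusted p = 0.13 with an estimated correlation), with Cd9 at -2.39 ± 0.20 and Timp2 at -3.59 ± 0.26. Secreted factors held to support tumours were lower for 9 of 18 genes and higher for 2 (camera adjusted p = 0.0028, and adjusted p = 0.12 with an estimated correlation). Gas6 and Pros1, both ligands of Mertk, changed by -3.69 ± 0.39 and -3.05 ± 0.27. Cholesterol synthesis genes were higher for 14 of 20 members and lower for 1 (camera adjusted p = 0.001, and adjusted p = 0.12 with an estimated correlation). Members included the epoxidase gene Sqle (2.98 ± 0.47) and the regulator Srebf2 (2.39 ± 0.29). Immediate-early and dissociation-stress genes were higher for 14 of 23 and lower for 2 (camera adjusted p = 0.0028, and adjusted p = 0.55 with an estimated correlation), with the nuclear receptor Nr4a1 higher (5.03 ± 0.44) and the small GTPase Rhob lower (-3.48 ± 0.28). Type I interferon response genes were higher for 10 of 30 and lower for 0, 7 and 0 when adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.9 with an estimated correlation). Among its members were Irf7 (1.52 ± 0.39) and Mx1 (1.62 ± 0.44).

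Lists of other cell types moved with this contrast. All 17 tested T and NK cell genes were higher in MDM (camera adjusted p = 7.7e-13, and adjusted p = 0.12 with an estimated correlation), with the cytotoxic granule genes Gzma (8.88 ± 0.68) and Prf1 (8.56 ± 0.69) and the NK receptor gene Ncr1 (9.35 ± 0.79) among the largest differences of all genes. Dendritic cell genes were higher for 11 of 12 (camera adjusted p = 2.5e-08, and adjusted p = 0.071 with an estimated correlation). Examples were Cd209a (8.04 ± 0.70) and Flt3 (6.57 ± 0.53). B cell genes were higher for 8 of 9 (camera adjusted p = 0.00012, and adjusted p = 0.2 with an estimated correlation). Members included Ms4a1 (7.09 ± 0.60). Endothelial and mural genes were higher for 5 of 9 (camera adjusted p = 0.029, and adjusted p = 0.12 with an estimated correlation). The adhesion gene Pecam1 was among them (2.98 ± 0.46). Outside the lists, Ear2, a gene of the eosinophil-associated ribonuclease family (8.90 ± 0.86), the keratin gene Krt80 (8.77 ± 0.76) and the adhesion gene L1cam (8.79 ± 0.78) were among the largest rises. Naalad2 (-6.69 ± 0.84), the fructose transporter gene Slc2a5 (-6.10 ± 0.64), Csmd3 (-5.95 ± 0.95) and Mlph (-5.86 ± 0.53) were among the largest falls. The remaining lists gave no camera call. Macrophage function lists among them were MHC class I presentation (6 rose and 2 fell of 15), inflammatory cytokine and NF-kB (11 and 7 of 24), immunosuppressive and alternative activation (10 and 4 of 23) and border-associated macrophage (6 and 2 of 12). Tissue and metabolism lists were extracellular matrix remodelling (6 and 7 of 22), glycolysis and hypoxia (6 and 5 of 26), oxidative phosphorylation (3 and 0 of 30), proliferation (2 and 3 of 32) and cholesterol efflux and lipid storage (5 and 6 of 18). Other cells were represented by neutrophil (1 and 1 of 10), oligodendrocyte (2 and 1 of 6), oligodendrocyte progenitor (0 and 1 of 11), astrocyte and neural stem cell (2 and 5 of 16), neuron (1 and 2 of 8) and red blood cell lists (0 and 0 of 5). Among single genes, Arg1, the arginase of alternatively activated macrophages, was higher in MDM (4.69 ± 0.79, adjusted p = 1e-04) and the lipid carrier gene Apoe lower (-1.05 ± 0.40, adjusted p = 0.04), a call that ended in 13 of the 21 fits that each left out 1 library. Spp1, which encodes osteopontin (-0.69 ± 0.46, adjusted p = 0.24), Cd274, which encodes PD-L1 (0.85 ± 0.38, adjusted p = 0.08), and the proliferation marker Mki67 (-1.10 ± 0.60, adjusted p = 0.15) did not pass the test.

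In all, 7356 of 17216 genes passed adjusted p under 0.05, 3952 higher and 3404 lower in MDM, and 8569 had an unadjusted p under 0.05. T and NK cell transcripts were unevenly spread over the MDM libraries: the list mean was 13.4 to 13.6 on the log2 scale in the 4 type 1 transplanted MDM libraries, 12.11 and 10.02 in the type 2 transplanted replicates 1 and 3, and 8.96 to 9.70 in the 3 spontaneous ones. Without the 4 type 1 transplanted MDM libraries 4719 genes were called, and without these and type 2 transplanted MDM replicate 1 the count was 3987, of which 3835 were called in the same direction in the full set. Without those 5 libraries 15 of 17 T and NK cell genes were still higher in MDM, Tmem119 changed by -3.02 ± 0.30 (adjusted p = 1.4e-05), Itgam by -0.88 ± 0.38 (adjusted p = 0.12) and Apoe by -0.58 ± 0.58 (adjusted p = 0.53). There lysosome and phagocytosis genes were lower for 14 of 27 and higher for 1 (median -0.68), disease-associated microglia genes lower for 10 of 27 and higher for 1, and secreted factors lower for 5 of 17 and higher for 1. Rescaling each library to the same total moved the median of all genes by 0.22 and made 67.4% of the calls higher in MDM against 53.7%, while quantile normalization made it 45.4%.

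**Figure D2:**
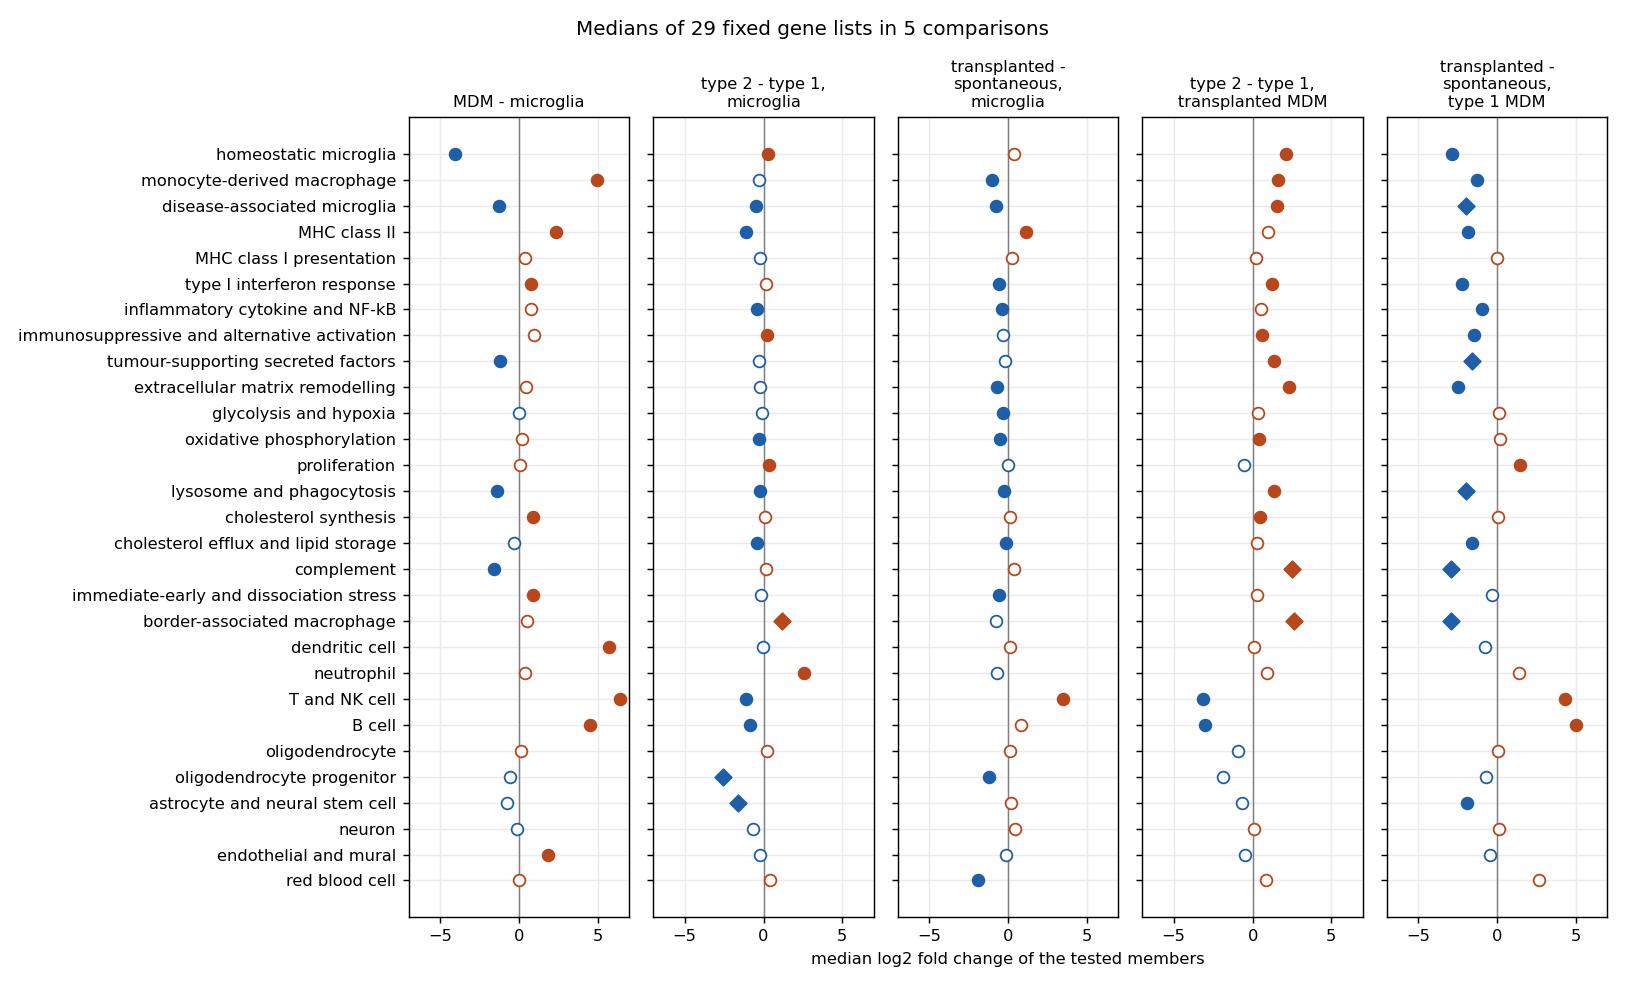
Median log2 fold change of the tested members of 29 gene lists in 5 comparisons, on a linear axis, with filled symbols for a camera adjusted p under 0.05, diamonds where it holds with an estimated correlation, and orange and blue for medians above 0 and at or below 0. Complement genes had medians of 2.52 in type 2 against type 1 transplanted MDM and -2.91 in transplanted against spontaneous type 1 MDM.

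Microglia of type 2 and type 1 tumours were compared over both models, 6 libraries against 6. Genes of neural progenitor cells, at low levels in these libraries, were among the largest falls in type 2. Sox2, a transcription factor of neural stem cells, stood at 3.27 ± 8.01 normalised counts in type 2 and 100 ± 55.5 in type 1 microglia (-5.77 ± 0.81, adjusted p = 0.0027), and Hes5, a Notch target of neural progenitors, at 1.42 ± 2.72 and 110 ± 103 (-5.57 ± 0.82, adjusted p = 0.0038). Nkd1, an inhibitor of Wnt signalling (-4.85 ± 0.73, adjusted p = 0.0038), the homeobox gene Dbx2 (-4.82 ± 0.81, adjusted p = 0.0097) and the protocadherin gene Pcdh17 (-4.78 ± 0.75, adjusted p = 0.0056) were also lower in type 2. Pou3f4, a neural transcription factor gene, had no reads in the 6 type 2 libraries and 54.7 ± 71.5 normalised counts in type 1, at least 19.3-fold lower against a floor of 3 reads per library (adjusted p = 0.011). In the other direction, Ptger3, a prostaglandin E receptor gene, rose in type 2 microglia (4.56 ± 0.82, adjusted p = 0.015), with Gpr165 (4.14 ± 0.84), the guanylate-binding protein gene Gbp10 (3.72 ± 0.70), the Myc-family gene Mycl (2.30 ± 0.43) and the zinc-finger gene Zkscan5 (1.60 ± 0.33).

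Of 11 oligodendrocyte progenitor genes tested, 3 fell and 8 were not called, with 7 lower when adjusted over the list alone (median -2.54, camera adjusted p = 1.7e-10, and adjusted p = 0.00071 with an estimated correlation). The lineage factors Olig1 (-3.23 ± 0.68) and Olig2 (-4.14 ± 0.73) and the phosphatase gene Ptprz1 (-3.88 ± 0.74) were the called members. Astrocyte and neural stem cell genes fell for 3 of 16 members, 8 when adjusted over the list alone (median -1.65, camera adjusted p = 3.4e-06, and adjusted p = 0.016 with an estimated correlation). Examples were Fabp7 (-3.67 ± 0.55) and Sox9 (-4.55 ± 0.91). The border-associated macrophage list, genes of the macrophages at the brain's surfaces, had a median of 1.20 with 0 of 12 members called, 4 higher when adjusted over the list alone (camera adjusted p = 3.7e-05, and adjusted p = 0.016 with an estimated correlation), and Mrc1, the mannose receptor, changed by 1.58 ± 0.49, adjusted p = 0.24. MHC class II genes had a median of -1.09 with 1 of 11 called lower, H2-Eb2 (-4.75 ± 0.80), and 7 lower when adjusted over the list alone (camera adjusted p = 6.1e-09, and adjusted p = 0.14 with an estimated correlation). H2-Ab1 itself changed by -1.12 ± 0.47, adjusted p = 0.48. Disease-associated microglia genes had 0 of 27 called and 6 lower when adjusted over the list alone (median -0.46, camera adjusted p = 3e-07, and adjusted p = 0.14 with an estimated correlation), with Clec7a at -1.09 ± 0.26, adjusted p = 0.078 and Itgax at -1.50 ± 0.36, adjusted p = 0.084. Abcg1, a cholesterol exporter gene, was the 1 called member of the cholesterol efflux list (-1.12 ± 0.21, adjusted p = 0.02). The homeostatic genes Tmem119 (0.04 ± 0.35, adjusted p = 0.99), P2ry12 (0.85 ± 0.64, adjusted p = 0.72) and Sall1 (0.18 ± 0.56, adjusted p = 0.95) did not pass the test, nor did Spp1 (-0.44 ± 0.56, adjusted p = 0.85), Arg1 (3.16 ± 0.97, adjusted p = 0.24) or Apoe (-0.43 ± 0.48, adjusted p = 0.82).

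Of 17 T and NK cell genes 1 was called lower in type 2, the NK receptor gene Klrb1c (-2.54 ± 0.52, adjusted p = 0.033), and the list median was -1.10 (camera adjusted p = 3.7e-05, and adjusted p = 0.41 with an estimated correlation). In the type 1 transplanted microglia libraries the mean of that list was 7.42, 8.37 and 3.47 in replicates 1, 2 and 4. Neutrophil genes had a median of 2.54 with 0 of 10 called (camera adjusted p = 3.7e-05, and adjusted p = 0.16 with an estimated correlation). Members included the granule gene Ngp (5.39 ± 1.63, adjusted p = 0.23). The camera test also called 8 other lists. Homeostatic microglia genes had a median of 0.28 (0 up and 0 down of 27, adjusted p = 0.0035), and inflammatory cytokine and NF-kB genes one of -0.40 (0 up and 0 down of 24, adjusted p = 0.01). Immunosuppressive and alternative activation genes had a median of 0.21 (0 up and 0 down of 23, adjusted p = 0.015), and oxidative phosphorylation genes one of -0.29 (0 up and 0 down of 30, adjusted p = 3.7e-05). Proliferation genes had a median of 0.37 (0 up and 0 down of 32, adjusted p = 0.015), and lysosome and phagocytosis genes one of -0.25 (0 up and 0 down of 27, adjusted p = 0.0028). Cholesterol efflux and lipid storage genes had a median of -0.42 (0 up and 1 down of 18, adjusted p = 0.0035), and B cell genes one of -0.85 (0 up and 0 down of 9, adjusted p = 0.032). The lowest of these 8 was adjusted p = 0.14 with an estimated correlation. In all 81 genes were called, 8 higher and 73 lower in type 2, and 1530 had an unadjusted p under 0.05. Without type 1 spontaneous replicate 2, whose monocyte-derived macrophage list mean was 11.56, and type 1 transplanted replicates 1 and 2, the count was 5, of which 1 was among the 81. There the oligodendrocyte progenitor median was -2.89 (camera adjusted p = 2.4e-10) and Sox2 changed by -5.32 ± 1.10 (adjusted p = 0.14). The T and NK cell median turned to 0.35 (camera adjusted p = 0.48), the B cell median to 0.09 (camera adjusted p = 0.77) and the proliferation median to -0.09 (camera adjusted p = 0.81). Camera calls also ended there for homeostatic microglia (median 0.17, adjusted p = 0.18), inflammatory cytokine (-0.01, adjusted p = 0.48) and cholesterol efflux genes (-0.28, adjusted p = 0.057). Leaving out single libraries gave 124 and 45 genes (type 1 spontaneous replicates 2 and 3), 34 and 39 (type 1 transplanted 1 and 2), 48 (type 2 spontaneous 3) and 44, 49 and 45 (type 2 transplanted 1, 2 and 3). In these fits 10 of the 19 called genes tracked by name kept their call throughout. Of the 12 fits, the call was lost in 10 for Olig1, 9 for Klrb1c and Zkscan5, 8 for Abcg1 and Gpr165, 7 for Sox9, 6 for Ptprz1, 5 for Mycl and 2 for Gbp10. The highest adjusted p was 0.12, for Olig1. Rescaling to the same total moved the median of all genes by 0.11.

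Microglia of transplanted and spontaneous tumours, 6 libraries against 6, differed in Spp1 and in MHC class II genes, among others. Spp1, the gene of the secreted phosphoprotein osteopontin (chromosome 5, 104435111 to 104441053), stood at 4402 ± 2323 normalised counts in transplanted and 187000 ± 137400 in spontaneous tumours (-5.27 ± 0.56, adjusted p = 5.5e-05). H2-Ab1 went the other way, at 179300 ± 118700 and 26530 ± 24950 (2.92 ± 0.47, adjusted p = 0.0026), together with H2-Aa (3.17 ± 0.49, adjusted p = 0.0019), H2-Eb1 (3.31 ± 0.51, adjusted p = 0.0019) and Ciita (3.37 ± 0.50, adjusted p = 0.0015). Gbp2b, an interferon-inducible guanylate-binding protein gene (chromosome 3, 142594816 to 142619179), was near the floor in spontaneous tumours (0.312 ± 0.763) and at 723 ± 1148 in transplanted ones (8.06 ± 0.66, adjusted p = 4.9e-06). Nlrp1a, which encodes an inflammasome sensor, rose from 8.18 ± 6.75 to 483 ± 141 (6.26 ± 0.62, adjusted p = 2.2e-05). Arg1 fell by 4.47 on the log2 scale (± 0.97, adjusted p = 0.025).

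MHC class II genes rose for 6 of 11 members and fell for 0, 7 and 0 when adjusted over the list alone (median 1.17, camera adjusted p = 3.7e-08, and adjusted p = 0.32 with an estimated correlation). Disease-associated microglia genes fell for 3 of 27 and rose for 0, 11 lower when adjusted over the list alone (camera adjusted p = 4.1e-10, and adjusted p = 0.32 with an estimated correlation), the called members being Spp1, Ch25h, which encodes cholesterol 25-hydroxylase (-3.56 ± 0.77), and the phosphate transporter gene Ank (-1.17 ± 0.29). The monocyte-derived macrophage list had 4 of 32 members lower and 0 higher (camera adjusted p = 4.8e-05, and adjusted p = 0.59 with an estimated correlation), with fibronectin, Fn1, at -3.83 ± 0.82, the annexin Anxa2 at -1.66 ± 0.39, Crip1 at -1.45 ± 0.31 and Lsp1 at -1.02 ± 0.25. Type I interferon response genes had a negative median, -0.59, with 5 lower when adjusted over the list alone (camera adjusted p = 0.0017, and adjusted p = 0.59 with an estimated correlation). Ifitm3 (-1.75 ± 0.46, adjusted p = 0.06) and Irf7 (-1.53 ± 0.48, adjusted p = 0.1) were not called. Immediate-early genes fell for 2 of 23 (camera adjusted p = 0.001, and adjusted p = 0.59 with an estimated correlation), Egr1 (-1.89 ± 0.41) and Ier2 (-1.51 ± 0.35). Oxidative phosphorylation genes had a median of -0.51 with 0 of 30 called (camera adjusted p = 3.7e-08, and adjusted p = 0.59 with an estimated correlation), and extracellular matrix genes fell for 2 of 22, Fn1 and the urokinase receptor gene Plaur (-1.66 ± 0.38) (camera adjusted p = 0.013, and adjusted p = 0.59 with an estimated correlation). Camera also called 5 other lists. Inflammatory cytokine and NF-kB genes had a median of -0.36 (0 up and 1 down of 24, adjusted p = 0.031), and glycolysis and hypoxia genes one of -0.29 (0 up and 0 down of 26, adjusted p = 0.047). Lysosome and phagocytosis genes had a median of -0.27 (0 up and 0 down of 27, adjusted p = 0.047), and cholesterol efflux and lipid storage genes one of -0.14 (0 up and 2 down of 18, adjusted p = 0.029). Red blood cell genes had a median of -1.93 (0 up and 0 down of 5, adjusted p = 0.039). The lowest of these was adjusted p = 0.35 with an estimated correlation. Ccl3, a chemokine gene (-1.96 ± 0.47), Colec12, a scavenger receptor gene of the border-associated list (-4.30 ± 0.86), and the apolipoprotein gene Apoc1 (-2.51 ± 0.52) fell as well.

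T and NK cell genes rose beside these groups, for 8 of 17 members with 0 lower, and for 14 with 1 lower when adjusted over the list alone (median 3.47, camera adjusted p = 6.3e-11, and adjusted p = 0.32 with an estimated correlation). Among its members were Il2rb (355 ± 423 against 14 ± 16.1, 4.95 ± 0.95), Cd2 (4.82 ± 0.80) and Cd3g (4.38 ± 0.87). Oligodendrocyte progenitor genes fell for 1 of 11, the proteoglycan gene Cspg4 (-4.64 ± 0.77, adjusted p = 0.0037; camera adjusted p = 0.043, and adjusted p = 0.34 with an estimated correlation). Serping1, the inhibitor of complement C1 (7.33 ± 1.17), Enpp5 (5.68 ± 0.77), Btnl6 (5.79 ± 0.82) and the T cell adaptor gene Sh2d2a (5.70 ± 0.77) were among the largest rises. The largest falls held the histocompatibility genes H2-Q2 (-6.73 ± 1.08) and H2-Q10 (-6.22 ± 1.05), the NK receptor gene Klrb1a (-5.58 ± 0.66) and Lgi2 (-5.05 ± 1.12). H2-Q10 stood at 4098 normalised counts in type 1 transplanted microglia replicate 1 and at 5.96 to 58.4 in the other 5 transplanted microglia libraries. Gbp2b, Nlrp1a, Btnl6, Klrb1a and the H2-Q genes belong to families of near-identical copies, as do Ear2, Klrb1c, C4b and Chil3, so their counts depend on how shared reads were assigned. Tmem119 (-0.05 ± 0.35, adjusted p = 0.96), P2ry12 (0.90 ± 0.64, adjusted p = 0.46), Apoe (-1.45 ± 0.48, adjusted p = 0.12) and Mki67 (-0.03 ± 0.74, adjusted p = 1) did not pass the test, and the signs for Tmem119 and Mki67 turned under another scaling.

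In all 317 genes were called, 173 higher and 144 lower in transplanted tumours, and 3339 had an unadjusted p under 0.05. Without the same 3 type 1 microglia libraries as above 122 genes were called, 95 of them among the 317 with the same sign. There Spp1 changed by -4.99 ± 0.70 (adjusted p = 0.0031), H2-Ab1 by 2.96 ± 0.59 (adjusted p = 0.038) and Arg1 by -3.28 ± 1.13 (adjusted p = 0.12), and 1 of 17 T and NK cell genes rose (median 1.76). Camera calls ended there for type I interferon response (median -0.40, adjusted p = 0.072), immediate-early (-0.23, adjusted p = 0.089), extracellular matrix (-0.39, adjusted p = 0.35) and inflammatory cytokine genes (-0.08, adjusted p = 0.48). They also ended for lysosome (-0.34, adjusted p = 0.067), glycolysis (-0.37, adjusted p = 0.089) and cholesterol efflux genes (-0.46, adjusted p = 0.089). Of the monocyte-derived macrophage list 1 of 32 members was then lower, Lsp1 (adjusted p = 0.049). Anxa2 (-1.74 ± 0.51, adjusted p = 0.093) and Crip1 (-1.45 ± 0.40, adjusted p = 0.085) lost their call with folds close to those of the full set, and Fn1 with a smaller one (-2.16 ± 0.77, adjusted p = 0.12). Disease-associated microglia genes were lower for 1 of 27. Ank (-1.22 ± 0.37, adjusted p = 0.097), Apoc1 (-2.71 ± 0.72, adjusted p = 0.08), Plaur (-1.59 ± 0.51, adjusted p = 0.11) and Ccl3 (-1.83 ± 0.59, adjusted p = 0.11) missed the threshold with folds near the earlier ones. So did Ch25h (-2.86 ± 0.96, adjusted p = 0.11), Egr1 (-1.42 ± 0.47, adjusted p = 0.11), Ier2 (-1.27 ± 0.40, adjusted p = 0.11), Lgi2 (-4.62 ± 1.40, adjusted p = 0.097), Cspg4 (-3.60 ± 0.98, adjusted p = 0.083), Colec12 (-3.00 ± 0.71, adjusted p = 0.065), Cd3g (2.33 ± 0.66, adjusted p = 0.087) and Il2rb (3.98 ± 1.06, adjusted p = 0.08), with smaller folds. Leaving out single libraries gave 532 and 209 genes (type 1 spontaneous 2 and 3), 173 and 189 (type 1 transplanted 1 and 4), 133, 141 and 1533 (type 2 spontaneous 1, 2 and 3) and 174 and 111 (type 2 transplanted 1 and 2). There 28 of 43 called genes tracked by name, Spp1, H2-Ab1 and Gbp2b among them, kept their call in every such fit. Of the 12 fits, the call was lost in 10 for Lsp1, 9 for Ank and Ier2, 8 for Anxa2 and Ccl3, 7 for Plaur, 6 for Lgi2, 4 for Arg1, Crip1 and Fn1, and 3 for Apoc1, Ch25h and Egr1. The highest adjusted p was 0.14, for Lsp1. Rescaling to the same total moved the median of all genes by 0.13 and made 64.8% of calls higher against 54.6%, or 53% under quantile normalization.

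A difference between tumour types in the effect of the model was called for few microglial genes, in a test that recovers 28.6% of simulated 4-fold changes. The interaction of type and model was called for 2 genes, with 1088 at an unadjusted p under 0.05. Wdfy1, a WD-repeat gene, had a log2 interaction of -2.39 ± 0.34, adjusted p = 0.014, and Rasgrp1, a Ras activator of lymphocytes named here after its value was seen, one of 7.65 ± 1.10 (adjusted p = 0.0138). Spp1 did not pass the test (-1.70 ± 1.13, adjusted p = 0.89). Of the lists, monocyte-derived macrophage genes had a median interaction of 2.29 with 0 of 32 members called (camera adjusted p = 3e-12, and adjusted p = 0.26 with an estimated correlation). Type 1 spontaneous replicate 2, whose mean for that list is given above, enters with a positive sign. Its median homeostatic marker stood at 53.2% of the mean of all microglia libraries. The interaction was not fitted without the libraries left out together above. Glycolysis and hypoxia genes had a median of -1.04 (camera adjusted p = 6.4e-08, and adjusted p = 0.21 with an estimated correlation). A further 12 lists passed camera with 0 members called in each. Homeostatic microglia genes had a median of -0.46 (0 up and 0 down of 27, adjusted p = 0.024), and disease-associated microglia genes one of -0.79 (0 up and 0 down of 27, adjusted p = 6e-08). MHC class II genes had a median of 0.85 (0 up and 0 down of 11, adjusted p = 0.025), and type I interferon response genes one of 1.26 (0 up and 0 down of 30, adjusted p = 2.3e-09). Oxidative phosphorylation genes had a median of -0.31 (0 up and 0 down of 30, adjusted p = 0.019), and lysosome and phagocytosis genes one of -0.40 (0 up and 0 down of 27, adjusted p = 0.004). Cholesterol efflux and lipid storage genes had a median of -0.65 (0 up and 0 down of 18, adjusted p = 0.0097), and border-associated macrophage genes one of 1.08 (0 up and 0 down of 12, adjusted p = 0.0025). Dendritic cell genes had a median of 1.92 (0 up and 0 down of 12, adjusted p = 3e-04), and neutrophil genes one of 2.21 (0 up and 0 down of 10, adjusted p = 0.019). B cell genes had a median of -1.52 (0 up and 0 down of 9, adjusted p = 0.021), and oligodendrocyte progenitor genes one of -1.72 (0 up and 0 down of 11, adjusted p = 0.0013). Across these the lowest was adjusted p = 0.12 with an estimated correlation. Leaving out single libraries gave 0 and 6 genes (type 1 spontaneous 2 and 3), 0 and 8 (type 1 transplanted 1 and 4), 1, 8 and 12 (type 2 spontaneous 1, 2 and 3) and 4, 0 and 0 (type 2 transplanted 1, 2 and 3). Limma voom on the recovered reads called 1. Wdfy1 lost its call in 5 and Rasgrp1 in 4 of the 12 fits that left out a library.

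MDM of type 2 and type 1 transplanted tumours, 2 libraries against 4, differed in complement and border-associated macrophage genes. The count rested on type 2 replicate 3, as given below. Arg1 stood at 4114 ± 1320 normalised counts in type 2 and 44.4 ± 17.2 in type 1 (6.55 ± 1.45, adjusted p = 0.013). Spp1 was 8.05-fold higher in type 2 (3.01 ± 0.84, adjusted p = 0.042). Ccl24, an eosinophil-attracting chemokine gene (6.37 ± 1.01, adjusted p = 0.0018), the monocyte chemokine gene Ccl2 (5.93 ± 1.16, adjusted p = 0.0064), the B cell chemokine gene Cxcl13 (6.78 ± 1.23, adjusted p = 0.004), Thbs1, which encodes thrombospondin (5.70 ± 1.27, adjusted p = 0.014), and Gfra2, a receptor subunit for neurturin (5.53 ± 0.90, adjusted p = 0.0021), were the largest rises beside Arg1. Tmem119 was higher in type 2 as well (2.54 ± 0.53, adjusted p = 0.0091), with Sall1 (4.12 ± 0.85), P2ry12 (3.39 ± 0.96) and Cx3cr1 (1.72 ± 0.37). Csf1r (0.78 ± 0.49, adjusted p = 0.39) and H2-Ab1 (0.99 ± 0.71, adjusted p = 0.47) did not pass the test, and the sign for H2-Ab1 turned under quantile normalization.

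Complement genes rose for 9 of 15 members and fell for 0, 13 and 0 when adjusted over the list alone (median 2.52, camera adjusted p = 1.4e-11, and adjusted p = 0.016 with an estimated correlation), with the C3a receptor gene C3ar1 at 3.51 ± 0.37, C1qb at 2.81 ± 0.61 and C4b at 3.21 ± 0.61. The border-associated macrophage list rose for 5 of 12 and fell for 0 (median 2.60, camera adjusted p = 1.5e-05, and adjusted p = 0.016 with an estimated correlation). Examples were Mrc1 (3.83 ± 0.73), the platelet factor Pf4 (4.60 ± 0.89), the scavenger receptor Stab1 (2.62 ± 0.55) and Cbr2 (4.19 ± 0.93). Lysosome and phagocytosis genes rose for 11 of 27, for example the cathepsins Ctss (2.31 ± 0.45) and Ctsl (2.25 ± 0.45), and fell for 1, the proton pump subunit Atp6v0d2 (-5.80 ± 0.91; camera adjusted p = 1.5e-12, and adjusted p = 0.095 with an estimated correlation). Homeostatic microglia genes rose for 12 of 27 and fell for 0 (camera adjusted p = 2.2e-09, and adjusted p = 0.23 with an estimated correlation). Disease-associated microglia genes rose for 8 of 27 (camera adjusted p = 3.7e-09, and adjusted p = 0.095 with an estimated correlation). Members included the lipid receptor Trem2 (3.36 ± 0.58), the glucan receptor Clec7a (2.07 ± 0.38) and Cd63 (2.74 ± 0.73). Extracellular matrix genes rose for 4 of 22, including the metalloproteinase Mmp14 (2.17 ± 0.39) and Sparc (3.15 ± 0.81; camera adjusted p = 1.3e-07, and adjusted p = 0.095 with an estimated correlation). Secreted factors rose for 4 of 18 (camera adjusted p = 0.012, and adjusted p = 0.12 with an estimated correlation). Among its members were Gas6 (3.84 ± 0.71) and the growth factor gene Pdgfa (2.11 ± 0.36).

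Another 5 lists moved by camera. Monocyte-derived macrophage genes had a median of 1.59 (2 up and 0 down of 32, adjusted p = 3.6e-05), and type I interferon response genes one of 1.21 (1 up and 0 down of 30, adjusted p = 1.5e-05). Immunosuppressive and alternative activation genes had a median of 0.62 (4 up and 0 down of 23, adjusted p = 0.02), and oxidative phosphorylation genes one of 0.40 (0 up and 0 down of 30, adjusted p = 0.037). Cholesterol synthesis genes had a median of 0.48 (0 up and 0 down of 20, adjusted p = 0.03). None kept it, the lowest being adjusted p = 0.32 with an estimated correlation. B cell genes fell for 1 of 9 members, the B lineage factor Pax5 (-4.65 ± 0.96, adjusted p = 0.0092), and for 8 when adjusted over the list alone (median -3.04, camera adjusted p = 7.2e-05, and adjusted p = 0.27 with an estimated correlation). T and NK cell genes fell for 1 of 17, Cd5 (235 ± 138 against 6728 ± 850, -4.96 ± 0.70, adjusted p = 0.00074), and for 7 when adjusted over the list alone (median -3.12, camera adjusted p = 5.8e-05, and adjusted p = 0.33 with an estimated correlation). Cd3e, at 657 ± 188 against 17200 ± 7226, narrowly missed the threshold (-4.65 ± 1.37, adjusted p = 0.051). Dtx1, a regulator of Notch signalling expressed in lymphocytes, fell from 1388 ± 368 to 8.34 ± 11.8 (-8.32 ± 1.46, adjusted p = 0.0034). Several genes had no reads in the 2 type 2 libraries and were lower there by at least 103-fold (Cd163l1), 102-fold (Dntt, the terminal transferase of lymphocyte precursors), 78.3-fold (Itga7), 75.6-fold (Sostdc1), 61.7-fold (Klk1) and 12.6-fold (Olig2) against a floor of 3 reads per library. Olig1 changed by -4.90 ± 1.02. With such genes at their bound the median of the oligodendrocyte progenitor list was -0.93 in place of -1.86. The homeostatic marker level, the median over markers relative to the mean of all microglia libraries, was 1.2% to 2.3% in the 4 type 1 libraries, and 2.3% and 26.3% in type 2 replicates 1 and 3. For genes higher in microglia than in MDM, such as complement, a tumour type effect cannot be told from microglial RNA in replicate 3. Any rise of macrophage genes may partly be dilution by lymphocyte RNA in type 1.

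In all 1018 genes were called, 509 in each direction, and 3620 had an unadjusted p under 0.05. The comparison rested on type 2 replicate 3: without it 79 genes were called, without type 2 replicate 1 there were 2011, and without type 1 replicates 2 and 3 there were 515 and 456. Of 40 called genes tracked by name, 8 kept their call in every such fit and most of the others, Arg1 (highest adjusted p = 0.21) and Tmem119 (0.35) among them, lost it without type 2 replicate 3. Spp1 lost it in 5 and P2ry12 in 4 of the 6 fits. When 1 type 2 library was left out, the other was taken to vary like the other groups. Rescaling to the same total moved the median of all genes by -0.26 and made 29.5% of calls higher against 50%, or 52.6% under quantile normalization.

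MDM of type 1 transplanted and spontaneous tumours, 4 libraries against 2, differed in lysosome, complement, disease-associated, border-associated macrophage and secreted factor genes. Spp1 fell from 106900 ± 44220 normalised counts in spontaneous to 1024 ± 371 in transplanted tumours (-6.72 ± 0.84, adjusted p = 1e-04), and Arg1 from 6122 ± 2531 to 44.4 ± 17.2 (-7.10 ± 1.45, adjusted p = 0.0032). Chil3, the chitinase-like gene of alternatively activated macrophages, fell from 130700 ± 126000 to 202 ± 95.4 (adjusted p = 0.0055). Thbs1 changed by -8.36 ± 1.27, adjusted p = 0.00036, Cxcl13 by -7.58 ± 1.23, adjusted p = 0.00058 and the Schlafen gene Slfn4 by -8.02 ± 2.02, adjusted p = 0.013. Tcim had no reads in the 4 transplanted libraries and was at least 60.4-fold lower against a floor of 3 reads per library. Microglial markers were lower in transplanted tumours: Tmem119 (-3.98 ± 0.53, adjusted p = 0.00014), Sall1 (-4.73 ± 0.85), Cx3cr1 (-2.95 ± 0.37) and P2ry12 (-3.31 ± 0.96), with Csf1r (-1.60 ± 0.49) and Itgam (-2.16 ± 0.52). H2-Ab1 changed by -1.97 ± 0.71, adjusted p = 0.074 and Mki67 by 2.45 ± 1.10, adjusted p = 0.16, neither of which passed the test.

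Lysosome and phagocytosis genes fell for 24 of 27 members and rose for 0, 25 lower when adjusted over the list alone (median -2.00, camera adjusted p = 2.2e-18, and adjusted p = 0.027 with an estimated correlation), with progranulin, Grn, at -3.27 ± 0.41, Lgmn at -3.52 ± 0.51 and the receptor kinase Axl at -3.43 ± 0.33. Complement genes fell for 13 of 15 and rose for 0 (median -2.91, camera adjusted p = 6.6e-12, and adjusted p = 0.02 with an estimated correlation). Examples were C3ar1 (-4.10 ± 0.37), C1qa (-3.12 ± 0.59) and C2 (-3.24 ± 0.54). Disease-associated microglia genes fell for 17 of 27 and rose for 0 (camera adjusted p = 1.2e-13, and adjusted p = 0.027 with an estimated correlation). Members included Ctsl (-3.05 ± 0.45) and Clec7a (-2.49 ± 0.38). Border-associated macrophage genes fell for 5 of 12 (camera adjusted p = 2.2e-05, and adjusted p = 0.02 with an estimated correlation), Mrc1 (-3.30 ± 0.73) and Stab1 (-3.00 ± 0.55) among them. Secreted factors fell for 5 of 18 (camera adjusted p = 0.00012, and adjusted p = 0.027 with an estimated correlation). Among its members were Pdgfa (-3.16 ± 0.36), Gas6 (-3.70 ± 0.71) and Pros1 (-2.52 ± 0.49). Homeostatic microglia genes fell for 14 of 27 (camera adjusted p = 6.6e-12, and adjusted p = 0.095 with an estimated correlation). Extracellular matrix genes fell for 11 of 22, Mmp14 (-3.15 ± 0.39) and Sparc (-4.24 ± 0.81) among them (camera adjusted p = 1.2e-08, and adjusted p = 0.054 with an estimated correlation). Type I interferon response genes fell for 14 of 30 (camera adjusted p = 5.4e-10, and adjusted p = 0.34 with an estimated correlation), the antiviral genes Oas2 (-4.00 ± 0.76), Oasl2 (-3.56 ± 0.61) and Mx1 (-3.34 ± 0.81) among them. MHC class II genes fell for 2 of 11, for example H2-DMb1 (-2.03 ± 0.35; camera adjusted p = 0.00089, and adjusted p = 0.35 with an estimated correlation). Inflammatory cytokine genes fell for 3 of 24, Ccl2 among them (-5.64 ± 1.16; camera adjusted p = 0.0012, and adjusted p = 0.47 with an estimated correlation), but the list median of -0.96 turned to 0.19 without type 1 spontaneous replicate 2.

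Camera called 5 further lists. Monocyte-derived macrophage genes had a median of -1.28 (0 up and 7 down of 32, adjusted p = 0.00017), and immunosuppressive and alternative activation genes one of -1.46 (0 up and 5 down of 23, adjusted p = 0.00049). Proliferation genes had a median of 1.48 (0 up and 0 down of 32, adjusted p = 6.5e-05), and cholesterol efflux and lipid storage genes one of -1.57 (0 up and 7 down of 18, adjusted p = 0.0015). Astrocyte and neural stem cell genes had a median of -1.88 (0 up and 3 down of 16, adjusted p = 0.001). Their lowest was adjusted p = 0.067 with an estimated correlation. Lymphocyte genes rose beside these falls. All 9 tested B cell genes rose (median 5.01, camera adjusted p = 3.3e-08, and adjusted p = 0.067 with an estimated correlation). Examples were Ms4a1 (4.86 ± 1.09), Pax5 (6.16 ± 0.96) and Cd79b (3.73 ± 0.64). T and NK cell genes rose for 12 of 17 and fell for 0 (median 4.28, camera adjusted p = 1.7e-09, and adjusted p = 0.1 with an estimated correlation), with Gzma at 30440 ± 5997 against 1461 ± 1580 (4.99 ± 1.24), Klrb1c at 4.77 ± 0.78, Cd3d at 4.41 ± 1.21 and Cd5 at 3.12 ± 0.70. Gbp2b rose from 1.06 ± 0.344 to 629 ± 248 (8.19 ± 0.98, adjusted p = 6.9e-05). Baiap3 (9.88 ± 1.63), the kinase gene Styk1 (8.49 ± 1.08) and Phactr3 (7.84 ± 1.39) were the other largest rises with fitted folds. Gzmc, a granzyme gene, and Klhl30 had no reads in the 2 spontaneous libraries and rose at least 90.4-fold and 81-fold against the same floor.

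**Figure D3:**
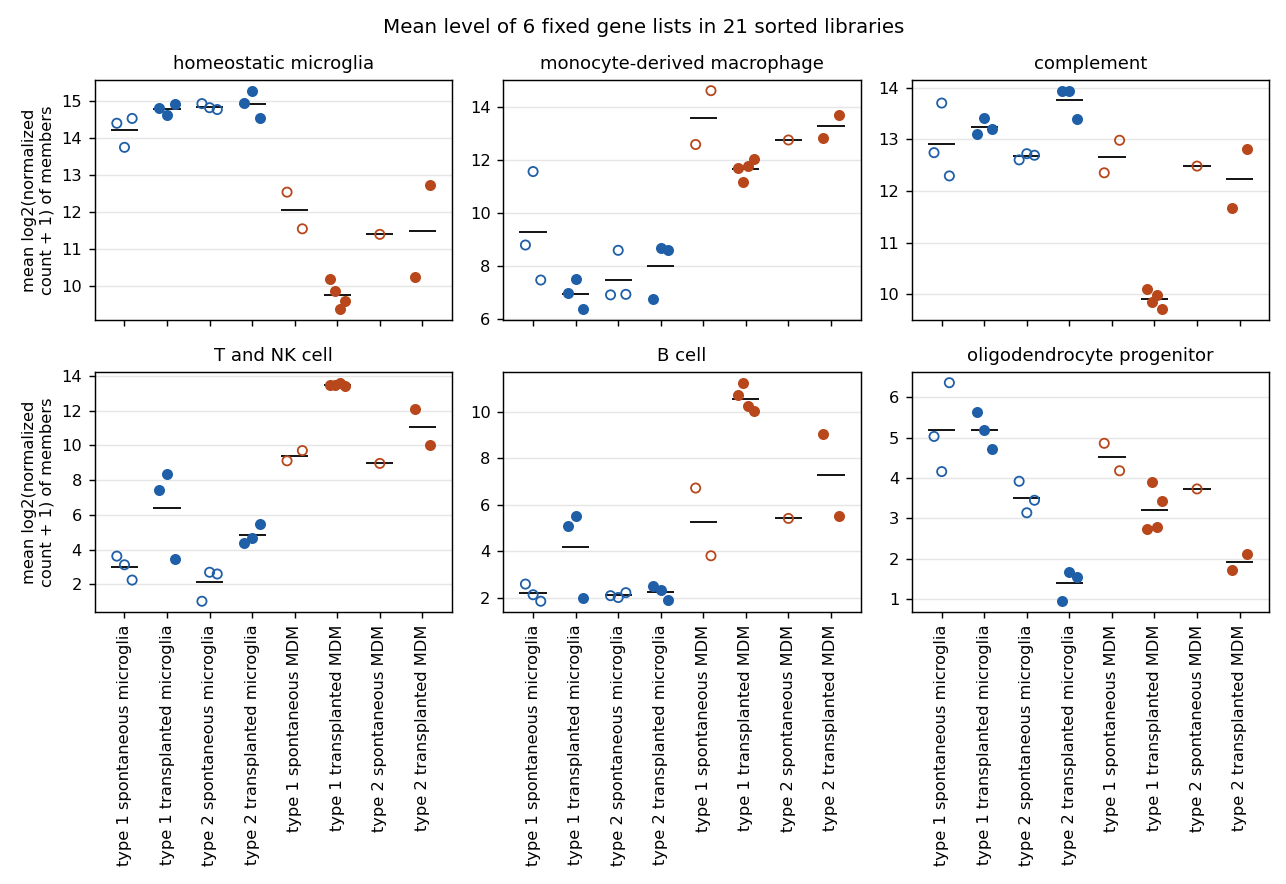
Mean log2(normalised count + 1) over the members of 6 gene lists in the 21 libraries, a point per library (blue microglia, orange MDM, open spontaneous, filled transplanted) with black bars for group means. The 4 type 1 transplanted MDM libraries lay between 13.4 and 13.6 for the T and NK cell list, above all 17 other libraries.

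In all 2366 genes were called, 996 higher and 1370 lower in transplanted tumours, and 4575 had an unadjusted p under 0.05. Without type 1 spontaneous replicate 2 the count was 942, and Arg1 (adjusted p = 0.052), Chil3 (0.097), Slfn4 (0.23), Ccl2 (0.16), Mx1 (0.38), Oas2 (0.089), Mrc1 (0.13), Itgam (0.096), Cd5 (0.072) and Ms4a1 (0.12) lost their call. Spp1 kept it in every fit that left out a library. Csf1r and P2ry12 each lost it in 4 of those 6 fits, Gzma in 1 and Cd3d in 2. Rescaling to the same total moved the median of all genes by 0.51 and made 75.5% of calls higher against 42.1%, or 44.5% under quantile normalization. The homeostatic marker level was 19.4% and 11.2% of microglia in spontaneous replicates 1 and 2 and 1.2% to 2.3% in the 4 transplanted libraries. The comparison could not be made without the lymphocyte-rich libraries, since these were all 4 of the transplanted side.

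Between microglia and type 1 MDM, which share no library, 42 genes were called higher in transplanted tumours in both comparisons, where independent lists would share 10. Another 41 were called lower in both (11.5 if independent) and 19 in opposite directions. The independent values are only a guide: same-numbered libraries may share a tumour, and lymphocyte genes, raised in both, were not set aside. The effect of the model itself differed between the cell types in type 1 tumours for 777 genes, 240 with a positive interaction and 537 with a negative one, and 3257 had an unadjusted p under 0.05. Negative values mean that transplanted against spontaneous libraries were lower, or less raised, in MDM than in microglia. All 4 transplanted MDM libraries were lymphocyte-rich, and homeostatic marker levels differed between the models, as given above. The interaction cannot tell such differences in RNA content from a change in the macrophages. Tmem119 (-4.16 ± 0.72, adjusted p = 0.0048), Sall1 (-5.26 ± 1.16, adjusted p = 0.016), Cx3cr1 (-2.57 ± 0.51, adjusted p = 0.0097), P2ry12 (-4.90 ± 1.32, adjusted p = 0.041) and Itgam (-2.58 ± 0.72, adjusted p = 0.048) had negative interactions. So did H2-Ab1 (-4.37 ± 0.97, adjusted p = 0.017) and H2-Aa (-4.58 ± 1.01, adjusted p = 0.016). Spp1 did not pass (-2.30 ± 1.16, adjusted p = 0.29). Complement genes had negative interactions for 8 of 15 members (median -2.67, camera adjusted p = 6.5e-11, and adjusted p = 0.044 with an estimated correlation). Members included C3ar1 (-3.69 ± 0.51), C2 (-4.33 ± 0.75) and C4b (-3.87 ± 0.84). Lysosome and phagocytosis genes had them for 11 of 27 (median -1.91, camera adjusted p = 1.3e-16, and adjusted p = 0.048 with an estimated correlation). Among its members were Mertk (-4.42 ± 0.75), Lgmn (-3.54 ± 0.71), Axl (-3.15 ± 0.46) and Grn (-2.92 ± 0.56). Secreted factors (3 of 18 negative, median -1.94, camera adjusted p = 0.00076, and adjusted p = 0.048 with an estimated correlation) and astrocyte and neural stem cell genes (1 of 16 negative, median -2.69, camera adjusted p = 0.00017, and adjusted p = 0.048 with an estimated correlation) followed. Positive interactions included the lymphocyte genes Styk1 (8.92 ± 1.48), Klrb1c (4.21 ± 1.07) and Cd79b (3.65 ± 0.88), with 2 of 9 B cell genes called (camera adjusted p = 0.00069, and adjusted p = 0.29 with an estimated correlation). In this interaction 8 more lists passed camera. Homeostatic microglia genes had a median of -2.81 (0 up and 11 down of 27, adjusted p = 5.3e-15), and disease-associated microglia genes one of -1.87 (0 up and 5 down of 27, adjusted p = 9.9e-09). MHC class II genes had a median of -2.68 (0 up and 7 down of 11, adjusted p = 1.6e-06), and extracellular matrix remodelling genes one of -1.95 (0 up and 3 down of 22, adjusted p = 8.3e-05). Oxidative phosphorylation genes had a median of 0.61 (0 up and 0 down of 30, adjusted p = 0.0048), and proliferation genes one of 1.55 (0 up and 0 down of 32, adjusted p = 0.00057). Cholesterol efflux and lipid storage genes had a median of -1.24 (0 up and 2 down of 18, adjusted p = 0.014), and red blood cell genes one of 4.31 (0 up and 0 down of 5, adjusted p = 0.037). The lowest among them was adjusted p = 0.09 with an estimated correlation. Leaving out single libraries gave 369 genes (type 1 spontaneous MDM 2), 508 and 479 (type 1 transplanted MDM 2 and 3) and 473, 477 and 475 (type 1 transplanted microglia 1, 2 and 4). P2ry12 lost its call in 11, Itgam in 10, Klrb1c in 9 and Cd79b in 4 of the 12 such fits. Rescaling moved the median of all genes by 0.46 and made 65.7% of calls positive against 30.9%, or 32.1% under quantile normalization.

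The effect of tumour type differed between the cell types in transplanted tumours for 129 genes, 68 with a higher and 61 with a lower value of type 2 against type 1 in MDM than in microglia, and 2698 had an unadjusted p under 0.05. Disease-associated microglia genes had positive interactions for 4 of 27 members, 24 when adjusted over the list alone (median 2.34, camera adjusted p = 1e-18, and adjusted p = 0.038 with an estimated correlation): Clec7a (4.23 ± 0.53, adjusted p = 0.0024), the adhesion gene Cadm1 (3.05 ± 0.51, adjusted p = 0.012), Trem2 (3.80 ± 0.80) and Cd9 (2.34 ± 0.50). C3ar1 (3.39 ± 0.51, adjusted p = 0.0074), Pdgfa (3.23 ± 0.49, adjusted p = 0.0074), H2-DMb1 (2.39 ± 0.49) and Ctss (2.69 ± 0.62) were positive as well. Besides these, 13 lists passed camera. Homeostatic microglia genes had a median of 1.89 (0 up and 0 down of 27, adjusted p = 1.1e-06), and MHC class II genes one of 1.60 (1 up and 0 down of 11, adjusted p = 0.0028). Inflammatory cytokine and NF-kB genes had a median of 0.64 (0 up and 0 down of 24, adjusted p = 0.027), and tumour-supporting secreted factors genes one of 1.52 (1 up and 0 down of 18, adjusted p = 0.0018). Extracellular matrix remodelling genes had a median of 2.78 (0 up and 0 down of 22, adjusted p = 2.8e-07), and glycolysis and hypoxia genes one of 0.98 (1 up and 0 down of 26, adjusted p = 0.00046). Oxidative phosphorylation genes had a median of 0.82 (0 up and 0 down of 30, adjusted p = 1.1e-05), and proliferation genes one of -0.89 (0 up and 0 down of 32, adjusted p = 0.026). Lysosome and phagocytosis genes had a median of 1.68 (1 up and 0 down of 27, adjusted p = 1.4e-16), and cholesterol efflux and lipid storage genes one of 0.95 (0 up and 0 down of 18, adjusted p = 0.0063). Complement genes had a median of 1.86 (1 up and 0 down of 15, adjusted p = 2.1e-06), and oligodendrocyte progenitor genes one of 3.09 (0 up and 0 down of 11, adjusted p = 0.014). Astrocyte and neural stem cell genes had a median of 1.63 (0 up and 0 down of 16, adjusted p = 0.0034). Their lowest value was adjusted p = 0.079 with an estimated correlation. Rab7b, a GTPase gene of late endosomes (5.13 ± 0.87), the metallothionein Mt2 (5.63 ± 1.13), Stra6l (5.14 ± 0.99) and Tmem51 (5.02 ± 1.02) were among the largest positive values and Susd2 (-9.86 ± 1.40) among the largest negative ones. Spp1 did not pass (4.30 ± 1.16, adjusted p = 0.084). Type 2 transplanted MDM replicate 3 had a homeostatic marker level of 26.3% of microglia, against 2.3% in replicate 1. The count rested on type 2 transplanted MDM: without replicate 3 it was 12 and without replicate 1 it was 992. It was 45 and 40 without type 1 MDM 2 and 3, and 27 and 40 without type 1 microglia 1 and 2. Without type 2 microglia 1, 2 and 3 it was 38, 31 and 43. Of 13 called genes tracked by name 3 kept their call in every such fit, Clec7a and C3ar1 among them. Ctss lost it in 11, Trem2 in 9, Cd9 and Mt2 in 8 and H2-DMb1 and Tmem51 in 7 of the 12 fits. Rescaling moved the median of all genes by -0.47 and made 22.3% of calls positive against 52.7%, or 57.9% under quantile normalization.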

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

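The tests of the 3 patterns weighed in this part, and the division test of the type by model interaction, were chosen only after the result was seen. Only type 1 transplanted MDM had the 4 libraries that the test for a library far from its group needs. Of 44 values tested there, 3 were found, and about 1 in 20 such values would be found by chance. The other groups were not tested. H2-Ab1 in type 1 transplanted MDM replicate 2 was 179000 normalised counts and the MHC class II list mean in that library was 14, a list that holds H2-Ab1. The extracellular matrix remodelling list mean in type 1 transplanted MDM replicate 1 was 7.44. The interactions called 2 genes for type by model in microglia, 129 for cell type by tumour type in transplanted tumours and 777 for cell type by model in type 1 tumours. In the last, P2ry12 had -4.90, Tmem119 -4.16, Sall1 -5.26, Cx3cr1 -2.57, Itgam -2.58 and H2-Ab1 -4.37, and the list medians were -1.94 for tumour-supporting secreted factors, -1.91 for lysosome and phagocytosis, -2.67 for complement and -2.69 for astrocyte and neural stem cell genes. The disease-associated microglia list had 2.34 in the cell type by tumour type interaction.

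The libraries were also divided at random with the group sizes kept. For MDM against microglia 1 of 100 divisions, the real one, called as many genes, with 3807 as the highest other count, and for model in microglia 1 of 100 with 36 as the highest other, so an accident of division can be excluded for both. For tumour type in microglia 5 of 100 divisions called at least as many and the highest other was 1346, and for the type by model interaction 18 of 100 with a highest of 3113. Chance cannot be excluded for these, and a division that calls many times the real count points to a structure of the samples.

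Lymphocyte transcripts were high in all 4 type 1 transplanted MDM libraries. RNA of lymphocytes in the sorted libraries remains in play, since 20 of 21 lymphocyte transcripts outside the lists, all but Klrk1, were higher in all 4 than in both type 1 spontaneous MDM libraries. Transcripts of T, NK and B cells rose together, for example Bcl11b (3760 against 304 normalised counts), Eomes (3920 against 164) and Pou2af1 (4170 against 176). Such a joint rise argues against a change in the macrophages alone as the source of these transcripts. Scaling of the libraries can be excluded as the whole cause: in transplanted against spontaneous type 1 MDM quantile normalization moved H2-Ab1 from -1.97 to -0.69 and left the T and NK cell median at 4.73, against 4.28 before. Whether these tumours held more lymphocytes stays open, with 2 of 3 type 1 transplanted microglia libraries above all 3 type 1 spontaneous ones. The falls of macrophage genes in these libraries may therefore partly be dilution by other RNA.

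A set of 6 genes was split by model in all 21 libraries: Gbp2b, Nlrp1a and Nlrp1c-ps higher and Spp1, Cxcl14 and H2af-ps2 lower in transplanted tumours. Same-numbered libraries of a class were taken as 1 tumour, 13 in all, an assumption. Only the real division, 1 of 100, split as many, and the highest other split 1, or 0 when single libraries were divided. This argues against a chance division. RNA of lymphocytes can be excluded for Nlrp1a and Nlrp1c-ps, near-identical copies that were lower in MDM than in microglia of type 1 transplanted tumours (-1.80 ± 0.44 and -2.02 ± 0.67). For Gbp2b (1.97 ± 0.89) it stays open. A difference in genetic background between the hosts also stays open: 0 of the split genes lay within 2 Mb of a split gene of another family, and the labels name no strain. That test covered only these 6 genes. Among genes called by model in microglia, Btnl6 (34507870), H2-Q2 (35342307) and H2-Q10 (35470089) start near each other on chromosome 17. The MHC class II gene H2-Ab1 (34263227) lies there too. A background difference at that locus was not tested.

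Progenitor transcripts were higher in type 1 than type 2 microglia. RNA of progenitor-like cells, possibly tumour cells, in the type 1 libraries remains in play. Of the 73 genes lower in type 2 microglia, 60 were also lower in type 2 transplanted MDM, where the median of all genes was -0.03. In limma-trend 21 of them were lower at an unadjusted p under 0.05 against 1 higher, and 8 were lower and called. The 73 include Klrb1c and H2-Eb2, and the type 1 transplanted MDM libraries were lymphocyte-rich, so this overlap does not single out progenitor cells. RNA of normal brain tissue stays open. The lower quartile of the 10 oligodendrocyte and neuron genes under 200 normalised counts was -1.08 against a median of -2.54 for oligodendrocyte progenitor genes, but astrocyte and neural stem cell genes fell too (median -1.65).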

How the results depend on the processing

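The settings tried after the result was seen were limma-trend on the deposited values, voom on the recovered reads and the fits without groups of libraries; the others were fixed before the data were examined. edgeR and DESeq2 on whole reads were not run. Counts of called genes stayed within a factor of 1.5 under quantile normalization, rescaling to the same total and sex as a covariate. For tumour type in microglia (81) the count was 32 with a filter at 50, 303 with array weights and 52 with only the compared groups in the fit, and for model in microglia (317) it was 169 without a filter, 2310 with array weights, 123 with only the compared groups and 196 with voom. For transplanted MDM by tumour type (1018) it was 560 with array weights and 327 with only the compared groups. The type by model interaction (2) gave 1 with a pseudocount of 8, with only the compared groups and with voom, and 182 with array weights. The cell type by tumour type interaction (129) gave 230 with a pseudocount of 8, 256 with array weights, 387 with only the compared groups, 237 on the deposited values and 63 with voom. The cause was not tested. MDM against microglia (7356) fell to 4719 without the type 1 transplanted MDM libraries and 3987 without type 2 transplanted MDM 1 as well, and without 3 type 1 microglia libraries tumour type in microglia gave 5 and model 122. With 1 library left out in turn the counts ran from 34 to 124 for tumour type in microglia, 111 to 1533 for model in microglia, 79 to 2011 for transplanted MDM by tumour type, 942 to 2145 for type 1 MDM by model, 0 to 12 for the type by model interaction, 12 to 992 for cell type by tumour type and 369 to 948 for cell type by model. The inflammatory cytokine and NF-kB list in transplanted against spontaneous in type 1 MDM ran from -1.76 to 0.19, turning sign without type 1 spontaneous MDM replicate 2. Of 115 list calls 15 were the same with an estimated correlation, 103 under quantile normalization and 111 with a pseudocount of 8, and the rest were weaker. With 1 library left out in turn, 114 of 1320 list results were weaker and 1 was reversed.

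Replicate numbers were not taken as pairing in the main fits, which treat all libraries as independent. Of 7 pairs with a correlation only 2 exceeded 0.1, the range being 0.02 to 0.23, but low values between different cell types cannot exclude pairing. As a hint from the data and not the design, 6 of 7 MDM libraries with a same-numbered microglia library correlated best with it, and all 8 pairs were of one sex. H2-Q10 and H2-Q2, described below, also went together in both replicates 1 of type 1 transplanted tumours. With a block by tumour, class and number together, MDM against microglia gave 6764. The cell type interactions were not fitted with that block. With a block by number alone the counts were 0 for tumour type in microglia, 16 for model in microglia, 0 for both MDM comparisons, where 1 residual degree of freedom was left, 0 for the type by model interaction, 18 for cell type by tumour type and 222 for cell type by model. The labels give no link between equal numbers of different classes, so calls lost here may only reflect the degrees of freedom spent. At an unadjusted p under 0.05 the block left 1693 genes for tumour type in microglia, 1430 and 2867 for tumour type and model in MDM, and 1188 for the type by model interaction.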

Other observations

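Some single genes rose beside Gbp2b in transplanted microglia, and no list of interferon gamma genes was tested. The type I interferon response list had a median of -0.59, or -0.40 without 3 type 1 microglia libraries (adjusted p = 0.072), and the T and NK cell list one of 3.47, or 1.76 without them. Cxcl9, a chemokine gene induced by interferon gamma, rose by 3.56 ± 0.52, adjusted p = 0.00131, with the guanylate-binding protein genes Gbp8 (4.07 ± 0.38), Gbp4 (2.88 ± 0.44) and Gbp6 (1.96 ± 0.36), the GTPase gene Iigp1 (2.75 ± 0.48) and the transcription factor Irf1 (1.35 ± 0.27). Of 10 Gbp genes other than Gbp2b, 4 rose in microglia and 3 in type 1 MDM, with medians of 1.99 and 1.11. Those not called in microglia were Gbp2, Gbp3, Gbp5, Gbp7, Gbp10 and Gbp11. Cxcl9 had a cell type by model interaction of -4.10 ± 1.07, adjusted p = 0.0348, a call lost in 9 of 12 fits that left out a library. All these genes were chosen after their values were seen, and Irf1 lost its call in 1 of 12 such fits and without the 3 libraries (1.22 ± 0.35, adjusted p = 0.087).

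The tests in this part were chosen only after the result was seen. H2-Q10 and H2-Q2, which share reads with near-identical copies, stood at 3421 and 1718 in type 1 transplanted MDM replicate 1 and at 4098 and 2194 in microglia replicate 1 of that class. The spontaneous libraries lay at 1737 to 3748 and 1078 to 1920, and the other 10 transplanted libraries at 5.96 to 238 and 0 to 119. For these genes the replicates numbered 1 of that class thus carry the values of the spontaneous libraries in both cell types, which bears on host background and on the meaning of the numbers. For Klrb1a they did not. Microglia replicate 1 stood at 10.9 against 19.6 to 419 in spontaneous microglia, and MDM replicate 1 at 567 against 44.2 to 299 in spontaneous MDM. Both also lay on the transplanted side for the 6 genes split by model, but those genes were chosen for splitting all libraries by model. That placement therefore says nothing about these replicates. Sequence variants in the reads of these libraries, not used here, would show whether they came from another host strain.

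Direct counts of lymphocytes, or single-cell RNA from the same sort, would bear on falls of macrophage genes in the type 1 transplanted MDM libraries. There 20 of 21 outside lymphocyte transcripts were higher. Such data would tell dilution by lymphocyte RNA from a change in the macrophages. More MDM libraries of type 2 and of spontaneous tumours would bear on the comparisons that rest on 1 or 2 libraries.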
